A study of Mus musculus with 32 samples.

How the data were processed

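Libraries were made from total RNA of purified mouse Foxp3-GFP+ regulatory T cells (Tregs) of Foxp3-IRES-GFP knock-in C57BL/6 mice aged 2.5 months, per the labels. The cells were either resting or had been cultured on coated antibodies to CD3 and CD28 with mouse IL-2 at 10 ng/ml for 18 h or 36 h. Cultured cells received no agonist or 1 of 4 agonists of tumour necrosis factor receptor superfamily members. The TNFR2 agonist was TNC-sc(mu)TNF80 (STAR2) at 12 ng/ml, the 4-1BB agonist was antibody 3H3 at 10 µg/ml, the DR3 agonist was its ligand TL1A at 12 ng/ml, and the OX40 agonist was OX40L at 100 ng/ml. Doses were not matched between agonists. RNA was isolated with the NucleoSpin RNA XS kit and libraries were made with the SMART-Seq v4 Ultra Low Input kit, per the labels. That kit amplifies full-length cDNA and does not mark strand.

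The submitters' processing notes name FastQC, Trimmomatic, STAR 2.5.3a and RSEM 1.2.28 with mouse genome build mm10. The annotation release and the counting strand setting are not given in the sources used here. The authors deposited 1 RSEM gene table per library, with expected counts, which are estimated reads per gene shared out among loci with multi-mapping reads and not scaled for depth or length. The same deposited tables hold TPM by the authors' RSEM run, scaled to the same sum in each library, which was used only to look at the composition of the tables. Each table listed 54087 genes, of which 53973 matched 1 gene of GENCODE release M21 on mm10, the source of the identifiers and positions printed here. Total expected counts per library ranged from 11880270 to 38083925. Genes that overlap, lie antisense to each other or have near-identical copies can share reads in such counts. Counting intervals and floors cover counting error only, because these libraries carry no molecular identifiers.

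Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 11 groups, which left 14313 genes, and libraries were scaled by TMM. A negative binomial model with 1 mean per group was fitted to all 32 libraries, so that the groups shared 1 estimate of the spread (common dispersion 0.00162, a biological coefficient of variation of 4%). Contrasts were tested with the robust quasi-likelihood F test, and p-values were adjusted by Benjamini-Hochberg over the genes tested; adjusted p values in the text come from this test unless another is named. A gene was called changed below an adjusted p of 0.05. Standard errors of log2 fold changes were derived from the F statistics, and levels are CPM, counts scaled by the TMM-adjusted library totals, as mean ± SD. The contrasts were control at 18 h and at 36 h against resting, control at 36 h against 18 h, each agonist against the control of its own time, the difference between the 36 h and 18 h effect of each agonist, and joint tests of differences among the 4 agonists at each time.

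A set of 32 gene lists was tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over the lists of a contrast. These covered NF-kB pathway and feedback genes, NF-kB target genes, the TNF receptor superfamily, TNF superfamily ligands, the Treg core signature, effector Treg genes, resting or naive T cell genes, T cell activation and immediate early genes, DNA replication and S phase, G2 and mitosis, cytokines, chemokines and their receptors, inhibitory receptors and ligands, cytotoxic genes, the IL-2 and STAT5 response and interferon-stimulated genes. The others covered anti-apoptotic genes, pro-apoptotic genes, glycolysis, oxidative phosphorylation, cholesterol biosynthesis and uptake, ribosome biogenesis and MYC targets, heat shock and chaperones, ER stress and amino acid response, the hypoxia response, p53 targets and mitochondrially encoded genes. Marker lists of B cells, of myeloid and dendritic cells, of CD8 T, NK and gamma-delta T cells, of conventional helper T cells and of erythroid cells and platelets completed the set. A list needed 5 tested members. Each camera test was repeated with a correlation estimated from the data; the p from that test is given where it ended a call.

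Groups, contrasts, the gene lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule took, in each activation or agonist contrast, the 12 largest and 12 smallest log2 fold changes among called genes with at least 5 CPM in the higher group and no overlap between replicates. It also took up to 4 list members with the smallest p per list, the receptors, ligands and Foxp3, and the 10 smallest p in each interaction or joint test. Symbols of predicted genes, clones and pseudogenes were excluded, and a gene once named could be used in other contrasts. Some genes that the rule took are not reported here.

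The fit was tested on simulated data drawn from the real means and library sizes, with 200 of 14034 genes changed. For the 4-1BB agonist at 36 h it recovered 42% of 50 genes changed 1.2-fold, 88% at 1.5-fold and 100% at 2-fold, with 8 false calls. For the OX40 agonist at 18 h, with 2 libraries, it recovered 40%, 78% and 98% at those folds, with 5 false calls. For the 4-1BB time interaction it recovered 24%, 74% and 94%, and for the joint test at 36 h 50%, 90% and 100%. With no gene changed, it made 0 calls for the DR3 agonist at 36 h.

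Replicate libraries were compared before they were averaged. Over genes, their counts differed by more than sampling noise in each pair (chi-square per degree of freedom 1.71 to 25.1), with Pearson r of log2 CPM of 0.998 to 0.999 across genes, which are not independent replicates. The labels do not state that replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. No sequencing batch or date was given in the sources used here. Alternatives were DESeq2 1.42.0, RLE size factors, no filter, a stricter filter, a minimum fold, only the groups compared, the replicate block, leaving out each library, and, added after the data were seen, 3 settings for a transcript at a ribosomal RNA locus.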

Results

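The data were 32 libraries made from total RNA of mouse Tregs, the CD4 T cells that carry the transcription factor Foxp3 and restrain other immune cells. Resting Tregs and control cultures at 18 h and 36 h had 3 libraries each. The cultures with an agonist of TNFR2, 4-1BB, DR3 or OX40 had 3 libraries per agonist and time, except the OX40 agonist at 18 h with 2, and these numbers hold for every mean, SD and fold change given here. Total expected counts were 11880270 to 15160995 in resting libraries, 17662427 to 20004351 in controls at 18 h and 21829871 to 24319121 in controls at 36 h. The agonist libraries held 13634395 to 21932343 at 18 h and 14785089 to 38083925 at 36 h. The first principal component took up 61.5% of the variance and parted resting from cultured cells, and the second, with 13.8%, parted 18 h from 36 h.

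**Figure D1:**
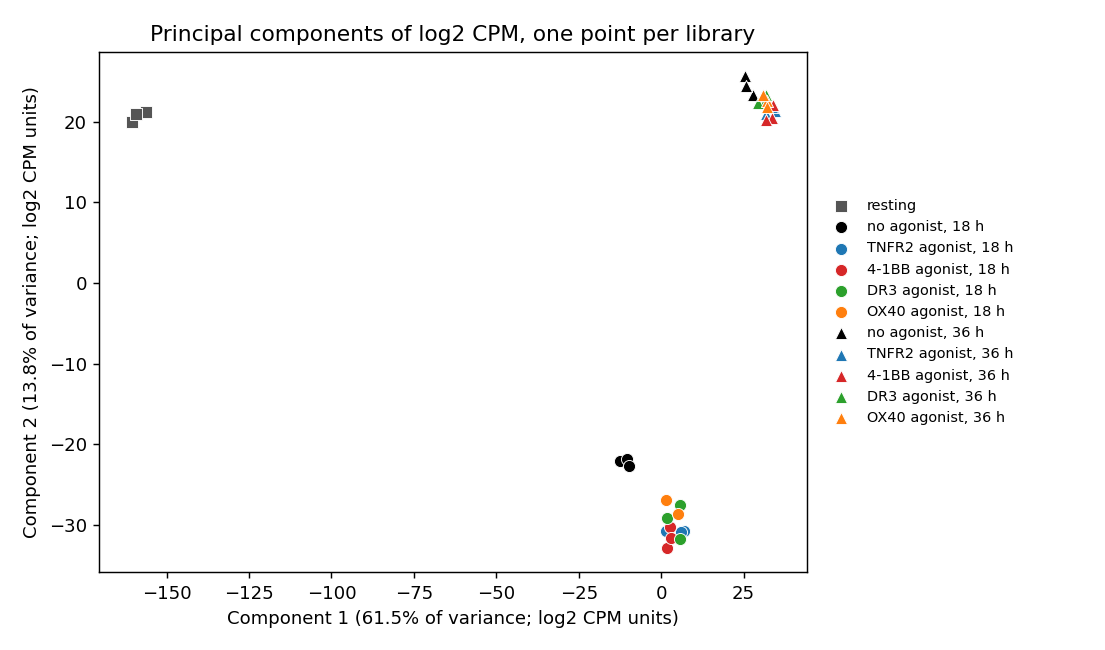
Scores of the 32 libraries on the first 2 principal components of log2 CPM, each point 1 library, coloured by group. Resting libraries lie at the far left, cultures at 18 h in the lower middle and cultures at 36 h at the upper right, with the controls slightly to the left of the agonist libraries of the same time.

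Whether Tregs express the 4 receptors that the agonists engage was asked first. TNFR2 (Tnfrsf1b), 4-1BB (Tnfrsf9), DR3 (Tnfrsf25) and OX40 (Tnfrsf4) are costimulatory members of the TNF receptor superfamily, and in mouse their genes all lie on chromosome 4. Tnfrsf9 (ENSMUSG00000028965, mm10 chromosome 4, 150914562 to 150946102) rose from 132.6 ± 7.67 CPM in resting cells to 565 ± 9.47 CPM in controls at 18 h, a log2 fold change of 2.09 ± 0.04 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p 1.98e-41). Tnfrsf4 (ENSMUSG00000029075, 156013843 to 156016612) rose likewise, from 165.8 ± 2.25 to 675.7 ± 15.4 CPM, and both stayed above resting cells at 36 h. Tnfrsf1b (ENSMUSG00000028599, 145213463 to 145246870) was already high at rest, at 377.3 ± 10.5 CPM, reached 505 ± 3.62 CPM at 18 h and was 328.1 ± 10.4 CPM at 36 h. Tnfrsf25 (ENSMUSG00000024793, 152115934 to 152120119) went the other way, from 70.03 ± 1.54 CPM at rest to 38.75 ± 0.559 CPM at 18 h and 16.7 ± 0.428 CPM at 36 h. Among their own ligands, Tnf rose from 56.78 ± 2.25 to 133 ± 6.43 CPM at 18 h and Tnfsf4 (OX40L) from 0.4731 ± 0.199 to 11.76 ± 0.705 CPM at 36 h. The DR3 ligand Tnfsf15 was near 1 CPM in controls (1.078 ± 0.261 at 18 h), and its difference from resting cells at 18 h did not pass (adjusted p 0.522).

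**Figure D2:**
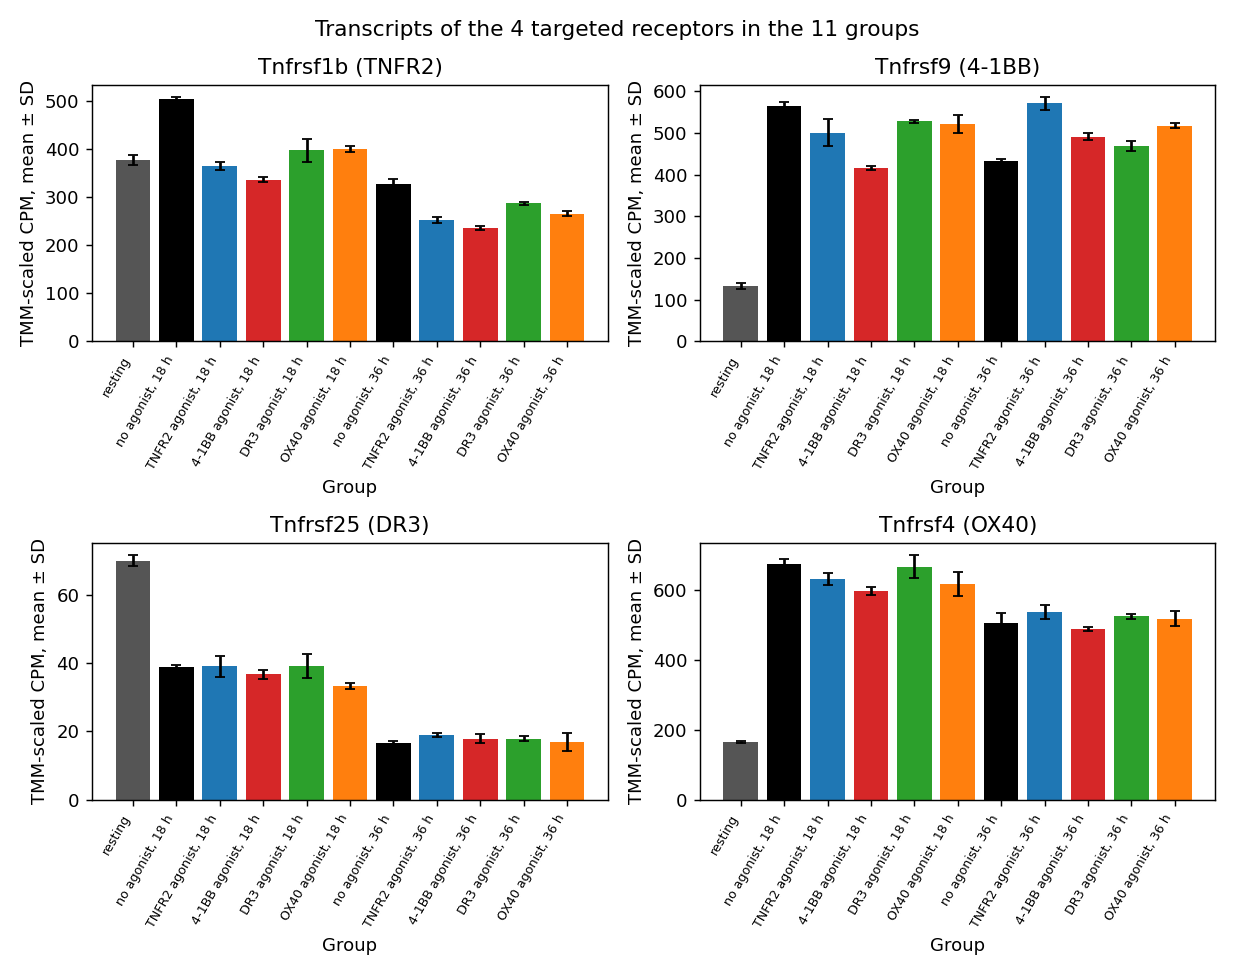
Levels of the 4 receptor transcripts (CPM, vertical axis from 0) in the 11 groups, bars showing the mean and error bars the SD over 2 or 3 libraries. Tnfrsf9 and Tnfrsf4 are higher in every cultured group than in resting cells, and Tnfrsf25 is lower.

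How Tregs cultured with stimulation through CD3 and CD28 and with IL-2 differed from resting Tregs was asked with the controls at 18 h. No group was cultured without stimulation. Effects of stimulation, of IL-2, of the culture itself and of the time since purification can therefore not be told apart in comparisons with resting cells. T cells that are stimulated leave quiescence, grow, and prepare to divide, which calls on MYC, ribosome assembly, glycolysis and sterol synthesis. They also switch surface receptors from those of recirculating cells, such as the IL-7 receptor, to those of activated cells, such as the high-affinity IL-2 receptor. Of 14313 genes tested, 11586 (80.9%) changed, 5848 higher and 5738 lower, and 2851 and 2954 of these by at least 2-fold. TMM scaling centres the fold changes (median over all genes −0.008 at 18 h and −0.01 at 36 h). The near-even numbers of higher and lower genes thus follow in part from the scaling. Higher and lower refer to shares of the RNA counted and not to amounts per cell. The stress transcription factor Atf3 (ENSMUSG00000026628, chromosome 1, 191170296 to 191218039) showed a log2 fold change of 6.99 ± 0.17 (adjusted p 7.61e-37), and the AP-1 factor Fosl1 one of 6.83 ± 0.23. Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273) fell from 573.9 ± 17.2 to 4.796 ± 0.52 CPM. Il2ra, the high-affinity IL-2 receptor chain, rose from 602.6 ± 16.3 to 3248 ± 11.5 CPM, and Irf4, a factor that drives effector Tregs, from 93.94 ± 4.43 to 874.2 ± 14.4 CPM. Il7r (ENSMUSG00000003882, chromosome 15, 9505788 to 9530176) fell from 452.9 ± 26.6 to 15.77 ± 0.132 CPM and Txnip, which limits glucose uptake, from 1008 ± 19.7 to 49.28 ± 1.17 CPM. The inflammatory chemokines Ccl3, Ccl4 and Ccl20 rose by 6.51 ± 0.28, 5.51 and 5.89 on the log2 scale, while the gut-homing receptor Ccr9 fell by 6.65. Foxp3 itself differed little, by 0.16 ± 0.04 (adjusted p 6.92e-05), and with a stricter filter on low counts, which shifted the median of 10336 genes by −0.12 at 18 h and at 36 h, its change was 0.04 and not called.

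Among the gene lists at 18 h, ribosome biogenesis and MYC targets rose in 30 of 30 tested members (median log2 fold change 2.24; camera adjusted p 2.12e-15), with Odc1, the rate-limiting enzyme of polyamine synthesis, going from 107.9 ± 5.77 to 1071 ± 23.1 CPM. DNA replication and S phase genes rose in 31 of 32 members (median 2.63; adjusted p 1.04e-13), and cholesterol biosynthesis and uptake in 29 of 30 (median 1.75; adjusted p 1.32e-09), with Cyp51 and Sqle up by 3.22 and 3.19. The resting or naive T cell list fell in 20 of 23 members and rose in 2 (median −1.85; adjusted p 1.26e-07). Interferon-stimulated genes fell in 27 of 30 members and rose in 3 (median −2.25; adjusted p 6.42e-07): Irf7, a driver of type I interferon, went from 72.42 ± 1.43 to 9.681 ± 0.963 CPM. Cytokines rose in 18 of 22 members (adjusted p 0.0128) and the ER stress and amino acid response in 21 of 27 (adjusted p 8.03e-05). These 7 calls also held with a correlation estimated from the data, and adjusted over the list alone every list had the same counts except chemokines and their receptors (13 higher and 9 lower instead of 12 and 9).

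The other 9 calls at 18 h were lost with an estimated correlation. Genes of G2 and mitosis rose in 29 of 30 members (adjusted p 4e-11; adjusted p 0.0779 with an estimated correlation), and oxidative phosphorylation in 39 of 39 (4.02e-10; 0.134 with an estimated correlation). Glycolysis genes rose in 18 of 24 members (0.000383; 0.176 with an estimated correlation), among them Hk2, the first enzyme of the pathway, from 8.74 ± 1.26 to 165.5 ± 4.42 CPM. NF-kB target genes rose in 20 of 28 (0.00273; 0.0779 with an estimated correlation), heat shock and chaperones in 10 of 15 (0.0141; 0.185) and the IL-2 and STAT5 response in 14 of 22 (0.03; 0.246). Markers of other cells fell: 11 of 14 of B cells (0.0128; 0.0779 with an estimated correlation), 14 of 16 of myeloid and dendritic cells (0.0146; 0.0513) and 8 of 10 of CD8 T, NK and gamma-delta T cells (0.0195; 0.0508). Ighm, the immunoglobulin mu chain, went from 721.4 to 302 CPM, and Klrb1c, the NK receptor NK1.1, was at least 32.8-fold lower in controls than in resting cells (floor of 3 counts over the group).

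The lists not called at 18 h had members moving both ways. The Treg core signature had 14 of 24 higher and 8 lower (adjusted p 0.365), effector Treg genes 16 and 11 of 27 (0.643), and activation and immediate early genes 15 and 12 of 27 (0.322). NF-kB pathway and feedback genes had 8 higher and 15 lower of 24 (0.22), with a log2 fold change of −2.19 ± 0.04 for the feedback inhibitor Tnfaip3 (A20) and of 1.39 ± 0.04 for Nfkb2. The TNF receptor superfamily had 11 higher and 6 lower of 17 (0.367), its ligands 8 and 3 of 14 (0.27), chemokines and their receptors 12 and 9 of 24 (0.583), and inhibitory receptors and ligands 8 and 10 of 18 (0.526). Anti-apoptotic genes had 7 higher and 6 lower of 13 (0.941), pro-apoptotic genes 6 and 8 of 19 (0.401), the hypoxia response 9 and 5 of 19 (0.401) and p53 targets 11 and 4 of 18 (0.15). Conventional helper T cell genes had 9 higher and 5 lower of 16 (0.746), and mitochondrially encoded genes 1 and 5 of 11 (0.401). Cytotoxic genes had 4 higher and 3 lower of 11 (0.783), with a median of −0.11, a mean of 0.09 and an upward test. Of 15 erythroid and platelet markers 3 were tested, too few for a list test; Hbb-bs had a log2 fold change of −2.15 ± 0.51 (adjusted p 0.000314), a call that DESeq2 did not make (−2.25), and Hba-a1 shares reads with its near-identical copy Hba-a2.

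At 36 h the question was how far the cultured and stimulated cells had moved towards division and effector function. Mitosis needs cyclin B, kinases such as Aurora B and topoisomerase II, and dividing T cells also make granzymes and cytokines. Compared with resting cells, 12092 genes changed (84.5%), 6072 higher and 6020 lower, and 3290 and 3459 of these by at least 2-fold. Top2a rose from 36.53 to 1179 ± 48.4 CPM (log2 fold change 5.01 ± 0.05, adjusted p 4.85e-49), and Ccnb1 and Aurkb by 6.63 ± 0.11 and 5.71. The cell cycle inhibitor Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727) rose as well, from 1.236 ± 0.428 to 142.7 ± 14.4 CPM. Ccl3 (ENSMUSG00000000982, chromosome 11, 83647844 to 83649355) reached 55.47 ± 3.51 CPM from 0.1594 CPM in resting cells, and the granzyme Gzmb rose by 3.96 ± 0.11. The cytokines Il1a and Il2 had 3 counts each over the resting libraries, so that their ratios of 404 (95% counting interval 138 to 1960) and 104 (35.4 to 506) are imprecise. Klf2, which keeps T cells in recirculation, went from 266.6 to 9.257 CPM, and the myeloid receptor Csf1r was lower by a ratio of 297 (52.7 to 11800) on 1 count in controls. Foxp3 was lower than in resting cells at 36 h, 368.7 ± 2.06 against 520.2 ± 16.1 CPM (−0.50 ± 0.04).

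The list results at 36 h resembled those at 18 h. Calls that held with an estimated correlation were those of S phase (32 of 32 members higher, adjusted p 2.89e-14), ribosome biogenesis (30 of 30 higher, 8.76e-14), cholesterol biosynthesis (29 of 30 higher, 1.2e-09), ER stress (20 of 27 higher, 7.53e-05) and cytokines (17 higher and 3 lower, 0.00458), and, downward, resting or naive T cell genes (21 of 23 lower, 1.27e-07) and interferon-stimulated genes (27 of 30 lower, 3.6e-07). G2 and mitosis rose in 30 of 30 members with a median log2 fold change of 5.10 (4.55e-14; adjusted p 0.052 with an estimated correlation). The p53 targets rose in 15 of 18 (0.00452; 0.111 with an estimated correlation), glycolysis in 18 of 24 (6.37e-05; 0.124), oxidative phosphorylation in 39 of 39 (1.36e-09; 0.124) and NF-kB targets in 21 of 28 (0.00261; 0.102). Heat shock genes (0.0127; 0.156 with an estimated correlation) and B cell markers (0.0186; 0.111 with an estimated correlation) were the other calls. Effector Treg genes had 12 higher and 12 lower (median 0.03, mean 0.21, downward test), anti-apoptotic genes 6 and 5 (median 0.09, mean 0.02, downward test) and pro-apoptotic genes 11 and 7 (median 0.39, mean −0.01, upward test), and none of these was called.

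What changed in control cultures between 18 h and 36 h is also the background against which the agonists act. Stearoyl-CoA desaturases make monounsaturated fatty acids, which dividing cells need for their membranes. GARP (Lrrc32), which presents latent TGF-beta on activated Tregs, and VISTA (Vsir) and Tigit, which restrain other T cells, are part of the suppressive machinery. Between the control groups 7468 genes changed (52.2%), 3657 higher and 3811 lower at 36 h, with a median absolute log2 fold change of 0.36. Scd1 (ENSMUSG00000037071, chromosome 19, 44394455 to 44407879) rose from 2.359 ± 0.423 to 34.4 ± 4.21 CPM and its neighbour Scd2 (44293674 to 44306864) from 169.2 ± 6.7 to 1008 ± 49.3 CPM. Ccnb2 (ENSMUSG00000032218, chromosome 9, 70407692 to 70421547) rose from 7.946 ± 0.889 to 70.92 ± 1.61 CPM. Lrrc32 (ENSMUSG00000090958, chromosome 7, 98489283 to 98502181) fell from 546.7 ± 21.5 to 200.2 ± 7.78 CPM, Vsir from 220 ± 6.94 to 73.46 ± 2.58 CPM, Tigit from 114.7 ± 3.62 to 55.28 ± 0.808 CPM and Foxp3 by 0.66 ± 0.04 on the log2 scale. The hypoxia genes Bnip3 and Egln3 rose by 2.06 ± 0.08 and 1.28 ± 0.05, and the T-box factor Eomes by 2.33. Lars2 and Rn7sk, with log2 fold changes of −2.30 ± 0.66 and −4.11 ± 0.85, stood beside a transcript at a ribosomal RNA locus on chromosome 17 that took up 10210, 26030 and 8114 CPM of the controls at 18 h and 3246, 741.4 and 849.4 CPM at 36 h; with that share as a covariate the change of Lars2 was −0.07 and not called.

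Of the lists, 18 were called between the control groups and 10 held with an estimated correlation. G2 and mitosis rose in 30 of 30 members (median 2.05; adjusted p 7.02e-35), S phase in 28 (9.61e-15), glycolysis in 19 of 24 (3.56e-10), p53 targets in 15 of 18 (1.33e-07), the hypoxia response in 15 of 19 (1.66e-07; 16 adjusted over the list alone), pro-apoptotic genes in 12 of 19 (0.00487) and cytokines in 12 of 22 (0.0116). Falling lists were the Treg core signature (17 of 24 lower and 3 higher, median −0.31, adjusted p 3.9e-07), ribosome biogenesis (22 of 30 lower, 2.73e-06) and inhibitory receptors and ligands (10 of 18 lower, 0.003). The remaining calls were lost with an estimated correlation, at adjusted p of 0.0505 for resting or naive T cell genes, NF-kB pathway genes and the IL-2 and STAT5 response, all falling. The TNF receptor superfamily (0.0643 with an estimated correlation) and interferon-stimulated genes (0.165) also fell, while cytotoxic genes (0.0566), cholesterol biosynthesis (0.0841) and ER stress (0.151) rose.

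What each agonist adds to stimulation was asked by comparing it with the control of the same time. All 4 receptors signal through TRAF adaptors to NF-kB, whose precursor p100 is encoded by Nfkb2 and whose inhibitors Nfkbia, Nfkbie and Tnfaip3 are themselves induced as feedback. At 18 h the TNFR2, 4-1BB, DR3 and OX40 agonists changed 4456, 3690, 2806 and 2724 genes, with median absolute log2 fold changes of 0.29, 0.32, 0.27 and 0.29 among them. At 36 h the counts were 3551, 3215, 1912 and 1908, with medians of 0.25, 0.28, 0.25 and 0.27. Changes of at least 2-fold were fewer, at 411, 470, 230 and 219 genes at 18 h and 265, 349, 127 and 143 at 36 h. Doses differed between agonists, so counts do not rank their potency. The ribosomal locus transcript differed between controls and most agonist libraries at 18 h. It took up 10210, 26030 and 8114 CPM in controls, 11860 CPM in TNFR2 agonist replicate 1 and 1407 to 6853 CPM in the other agonist libraries. At 36 h it took up 741.4 to 3246 CPM in controls and 1206 to 15000 CPM in agonist libraries. Without the 6 libraries with over 10000 CPM of a transcript at a ribosomal RNA locus, which leaves 1 control library at 18 h, the counts at 18 h were 1876, 1873, 1150 and 1181, and without the 5 with over 11000 CPM the TNFR2 count was 2945. Without OX40 agonist replicate 2 at 18 h the OX40 count was 1491; at 36 h the DR3 count was 1223 without DR3 agonist replicate 1 and 1191 without control replicate 2.

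A common set of genes marked all 8 agonist comparisons. Among them was Scin (ENSMUSG00000002565, chromosome 12, 40059769 to 40134228), which encodes the actin-severing protein scinderin. It went from 12.17 ± 1.06 CPM in controls to 119.3 ± 5.49 CPM with the 4-1BB agonist at 18 h and from 14.1 ± 0.527 to 140.9 ± 0.879 CPM at 36 h, and its log2 fold change was between 2.12 and 3.32 in all comparisons. Cacnb3 (ENSMUSG00000003352, chromosome 15, 98630840 to 98644529), a calcium channel beta subunit, rose from 4.179 ± 0.423 to 29.17, 64.06 ± 2.75, 18.32 and 20.66 CPM at 18 h in the order TNFR2, 4-1BB, DR3 and OX40. Rises in each comparison were also seen for Zbtb46 (1.08 to 2.11), Casz1 (1.25 to 2.13), Sema4a (1.18 to 2.40), the vasodilator peptide gene Adm (1.05 to 3.40) and the death receptor Fas (0.50 to 1.32). Il10, the suppressive cytokine (ENSMUSG00000016529, chromosome 1, 131019845 to 131024974), fell in each, from 31.9 ± 2.4 CPM to 12.22 ± 2.26 with the TNFR2 and 11.21 ± 1.45 with the 4-1BB agonist at 18 h. The ectonucleotidase Nt5e (CD73), the homing receptor Cxcr6, the death inducer Bcl2l11 (Bim) and the survival gene Bcl2 also fell in each comparison. Tnfrsf1b fell in all 8, with log2 fold changes of −0.19 to −0.58, and the ligand gene Tnfsf15 rose in all 8, by 1.24 to 2.09. Foxp3 moved by at most 0.15 at 18 h, called for the TNFR2 (0.14, adjusted p 0.00127), 4-1BB (0.14) and OX40 (0.15) agonists, and was not called at 36 h. Without the 6 libraries richest in the ribosomal locus transcript, which left 1 control library at 18 h, the folds were 0.16, 0.14 and 0.14 and no longer called (adjusted p 0.0855, 0.126 and 0.17). Without the 5 richest all 3 were called (0.0129, 0.0248 and 0.0394). The OX40 call also ended without OX40 agonist replicate 2 at 18 h (0.08), and the DR3 agonist gained one without its replicate 1 at 18 h (0.12, adjusted p 0.0332).

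**Figure D3:**
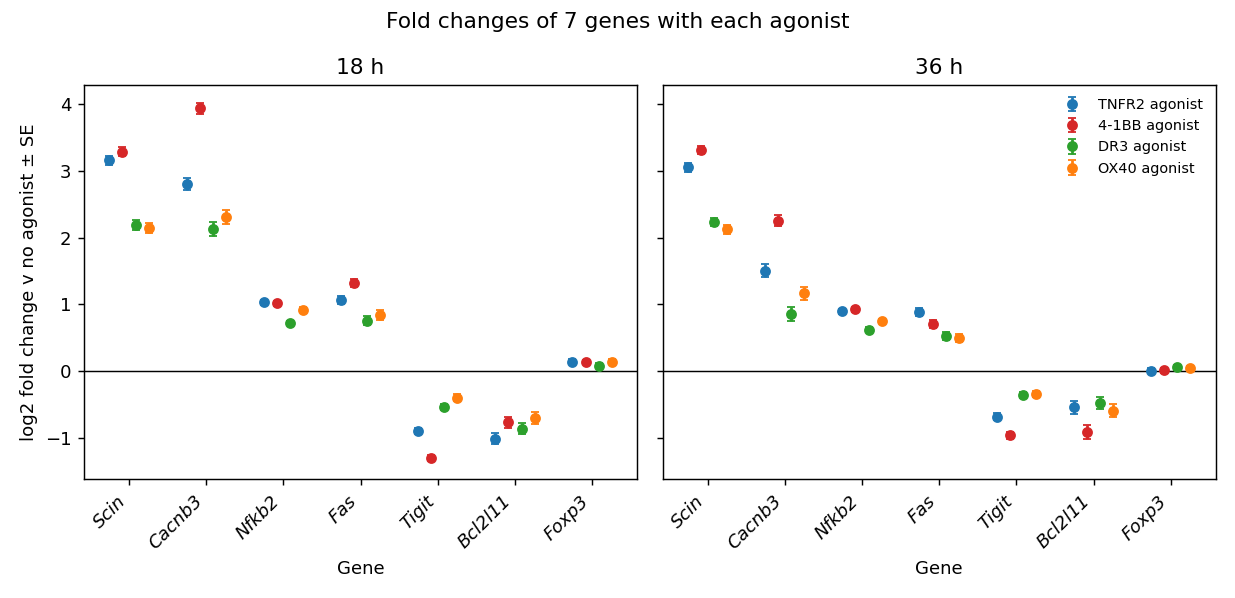
Log2 fold change against the control of the same time (vertical axis) of 7 genes with each agonist at 18 h and 36 h, points showing the estimate and error bars its standard error. Scin, Cacnb3, Nfkb2 and Fas are above 0 and Tigit and Bcl2l11 below 0 in all 8 comparisons, while Foxp3 stays near 0.

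The TNFR2 agonist STAR2 engages the receptor through which TNF expands Tregs. At 18 h 2265 genes were higher and 2191 lower, and at 36 h 1854 and 1697. Nfkb2 (ENSMUSG00000025225, chromosome 19, 46304320 to 46312385) went from 373 ± 4.58 to 762.4 ± 19.5 CPM at 18 h (log2 fold change 1.03 ± 0.04, adjusted p 2.51e-28). Icam1 rose by 1.00 (adjusted p 1.05e-26) and Jun by 1.06, whereas Nt5e fell from 210 to 110.5 CPM and Bcl2l11 fell with an adjusted p of 4.73e-14. The homing receptor Cxcr6 had a log2 fold change of −1.40 at 18 h. At 36 h this agonist raised Tnfrsf9 from 433.7 ± 5.23 to 571.3 ± 15.1 CPM (0.40; adjusted p 1.26e-12), the melanoregulin gene Mreg by 2.27 and the invariant chain Cd74 from 45.87 to 86.17 CPM.

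The 4-1BB agonist antibody engages a receptor that marks recently stimulated Tregs. It changed 1814 genes upward and 1876 downward at 18 h, and 1566 and 1649 at 36 h. Csf2 (GM-CSF; ENSMUSG00000018916, chromosome 11, 54247271 to 54249667) went from 0.7037 ± 0.15 to 6.244 ± 0.492 CPM at 18 h (3.13 ± 0.19, adjusted p 5.58e-19) and from 2.395 ± 0.235 to 12.96 ± 0.749 CPM at 36 h. The type 2 cytokine Il13 (ENSMUSG00000020383, chromosome 11, 53631324 to 53634702) rose from 0.9493 ± 0.241 to 5.799 ± 0.55 CPM at 36 h. Tigit (ENSMUSG00000071552, chromosome 16, 43648867 to 43664146) fell from 114.7 ± 3.62 to 46.41 ± 1.57 CPM at 18 h (−1.31 ± 0.05, adjusted p 4.24e-28). Ly75 (DEC-205) rose by 1.40 and Cd80, a ligand of CTLA-4 and CD28, by 1.71. The receptor Tnfrsf9 itself fell by 0.44 on the log2 scale at 18 h and Tnfrsf1b from 505 ± 3.62 to 336.7 ± 4.84 CPM. Lars2 and Rn7sk were among the lowest (−2.09 ± 0.66 and −2.15), beside the ribosomal locus transcript; with its share as a covariate they were at −0.49 and −0.22 and not called, and without control replicate 2 at 18 h at −1.55 and −1.53 and not called either.

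TL1A is the ligand of DR3 and expands Tregs in mice. It changed 1383 genes upward and 1423 downward at 18 h, and 997 and 915 at 36 h. Il9 (ENSMUSG00000021538, chromosome 13, 56479277 to 56482246), a cytokine that acts on mast cells, rose at 18 h from 0.2656 ± 0.0533 to 5.309 ± 1.03 CPM (4.28 ± 0.28, adjusted p 9.64e-17). Il9 also rose with the TNFR2, 4-1BB and OX40 agonists at 18 h (2.67, 3.71 and 2.06), and in pairwise tests the DR3 agonist gave more than each of these (adjusted p 1.63e-07, 0.0298 and 1.68e-08). Icam1 rose by 0.89 (adjusted p 1.39e-23) and Ebi3, a chain of IL-35 and IL-27, by 1.23. Eomes rose by 1.00 at 18 h and had a log2 fold change of −0.42 at 36 h. At 36 h Igfbp4 and Ly6c1 fell, with log2 fold changes of −1.33 and −1.02. Rpph1, a structural RNA, was 1.34 and 1.60 higher at the respective times.

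OX40L engages a receptor whose signals favour T cell survival and expansion. With 2 libraries at 18 h, 1334 genes were higher and 1390 lower, and with 3 libraries at 36 h, 1019 and 889. Cacnb3 rose by 2.31 ± 0.10 at 18 h (adjusted p 2.49e-23) and Scin by 2.12 at 36 h (adjusted p 1.57e-28). Bhlhe40, a factor that permits cytokine production, rose by 0.99 and 1.04, and Eomes by 1.34 at 18 h. Il2 rose by 1.14 at 18 h and 0.74 at 36 h, and with the DR3 agonist by 1.02 and 0.61. Il1a fell by 1.39 and 1.36 on the log2 scale and Klf2 by 1.09 at 36 h. Il9 was not called at 36 h (0.46, adjusted p 0.251). Lars2 had a log2 fold change of −2.19 ± 0.77 at 18 h (adjusted p 0.0496), which with the ribosomal locus share as a covariate was −0.28 and not called.

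The NF-kB lists rose with every agonist. NF-kB pathway and feedback genes had 13 to 15 of 24 members higher and 1 to 5 lower (adjusted over the list alone, 14 to 16 and 2 to 6), with camera adjusted p of 2.42e-10 to 1.49e-07, all of which held with an estimated correlation. Nfkbia rose by 0.50 to 0.88, Nfkbie by 0.48 to 0.95 and Tnfaip3 by 0.31 to 0.91 across the 8 comparisons. NF-kB target genes had 13 to 18 of 28 members higher and 2 to 7 lower (adjusted over the list alone, 15 to 20 and 2 to 7), with adjusted p of 1.12e-12 to 5.68e-05. That call was lost with an estimated correlation only for the OX40 agonist at 36 h (0.07). Cd83 rose by 0.55 to 1.05 and Gadd45b by 0.28 to 0.99, while Tnf, itself on the list, fell with each agonist (−0.31 to −0.49).

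Resting or naive T cell genes and the Treg core signature fell with every agonist. Of 23 resting or naive genes, 11 to 15 were lower and 2 to 5 higher (adjusted over the list alone, 12 to 17 and 2 to 6), with adjusted p of 2.22e-09 to 0.00189. This held with an estimated correlation for TNFR2 at 18 h, 4-1BB at 36 h and DR3 at both times, but not for 4-1BB or OX40 at 18 h (0.122 and 0.119) or TNFR2 or OX40 at 36 h (0.0676 and 0.112). The lymph node homing receptor Ccr7 went against the list and rose in all 8 (0.13 to 0.49). In the Treg core signature 11 to 14 of 24 members were lower and 4 to 7 higher (adjusted over the list alone, 11 to 15 and 4 to 7), with adjusted p of 6.86e-06 to 0.0256. Only the 4-1BB and DR3 calls at 36 h held with an estimated correlation, at 0.0176 and 0.00679; the others were at 0.0687 to 0.148. Nt5e and Tigit fell throughout; of members chosen after their values were seen, Ctla4 fell at 18 h (−0.32 to −0.60) and the Helios gene Ikzf2 was not called in any comparison. Effector Treg genes fell for TNFR2 and 4-1BB at 18 h and 4-1BB at 36 h (adjusted p 0.00795, 0.0122 and 0.0262; 0.153 to 0.192 with an estimated correlation), with Batf and Bhlhe40 rising and Il10 and Tigit falling inside the list. Inhibitory receptors and ligands fell with TNFR2 at 18 h and 4-1BB at 36 h (0.0195 and 0.0417; 0.0851 and 0.102 with an estimated correlation). The latter call ended without control replicate 2 or 4-1BB agonist replicate 2 at 36 h (0.0594 and 0.0652), and without OX40 agonist replicate 1 at 18 h those of OX40 at 18 h for resting or naive genes and the core signature did (0.0593 and 0.145).

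Proliferation genes rose at 18 h. Of 32 S phase genes, 24, 17, 16 and 19 were higher and 0 lower with the TNFR2, 4-1BB, DR3 and OX40 agonists (25, 19, 22 and 21 adjusted over the list alone), with adjusted p of 3.21e-08, 8.73e-05, 1.01e-06 and 3.34e-08, none of which held with an estimated correlation (0.115 to 0.222). Uhrf1, which maintains DNA methylation at replication, rose by 0.22 to 0.35. G2 and mitosis genes were higher in 25, 13, 9 and 12 of 30 members (27, 14, 17 and 15 adjusted over the list alone; adjusted p 1.82e-07 to 0.00185; 0.217 to 0.481 with an estimated correlation) and were not called at 36 h with any agonist. At 36 h S phase genes were called for 4-1BB and OX40 (0.0019 and 0.00315; 0.389 and 0.455 with an estimated correlation). Ribosome biogenesis genes rose at 18 h in 12 to 16 of 30 members (3.1e-07 to 0.00162; 0.0752 to 0.195 with an estimated correlation) and heat shock genes in 5 to 7 of 15 (0.000121 to 0.00795; 0.0953 to 0.217). The IL-2 and STAT5 response rose at 18 h in 10 or 11 of 22 members (camera adjusted p 0.0142 to 0.0468, and 0.245 to 0.321 with an estimated correlation), with Stat5a, which is also among the NF-kB target genes, up by 0.39 to 0.69. None of these last 3 lists was called at 36 h. Oxidative phosphorylation rose at 18 h with each agonist and at 36 h with TNFR2 (0.000592 to 0.0447; 0.404 to 0.655 with an estimated correlation). The oxidative phosphorylation call at 18 h ended for TNFR2, 4-1BB and OX40 without the 6 libraries richest in the ribosomal locus transcript. That setting left 1 control library at 18 h. Single libraries at 18 h carried some of the calls named here. The IL-2 and STAT5 call for 4-1BB ended without control replicate 2 or 3 or 4-1BB agonist replicate 1 or 3 (0.0514 to 0.0768), and for OX40 without OX40 agonist replicate 2 (0.0788). The oxidative phosphorylation call ended for 4-1BB without control replicate 1 (0.101) or 4-1BB agonist replicate 3 (0.0753), and for OX40 without control replicate 1 (0.17) or OX40 agonist replicate 1 (0.571).

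Anti-apoptotic genes rose as a list in all 8 comparisons, with 5 to 8 of 13 members higher (camera adjusted p 0.000247 to 0.0424, and 0.0589 to 0.26 with an estimated correlation). Bcl2l1 (Bcl-xL) rose by 0.16 to 0.58 while Bcl2 fell. Bcl2l1, Birc2, Gadd45b and Tnfaip3, the members higher in all 8, are also on the NF-kB lists. The anti-apoptotic calls are thus not independent of the rise of those lists. Glycolysis genes were not called at 18 h and rose at 36 h with TNFR2, 4-1BB, DR3 and OX40 in 16, 11, 7 and 14 of 24 members (5.07e-05, 0.000349, 0.00831 and 1.55e-08; 0.07 to 0.377 with an estimated correlation). The difference between the times was called for this list in all 4 interactions (2.27e-08 to 0.0012), and none of these held with an estimated correlation (0.09 to 0.258). The p53 targets rose at 36 h with TNFR2 (0.000142; 0.0676 with an estimated correlation) and DR3 (0.00011; held at 0.0495 with an estimated correlation), and Phlda3 rose by 0.38 to 0.85 at that time; the difference between the times was called for TNFR2 and DR3 (0.00728 and 0.00384) and lost with an estimated correlation (0.12 and 0.159). Immediate early genes fell as a list at 18 h with each agonist (camera adjusted p 8.73e-05 to 0.0472, and 0.137 to 0.473 with an estimated correlation). At 36 h they rose with TNFR2 (camera adjusted p 0.00504, and 0.318 with an estimated correlation). Members went both ways: of those called in all 8 comparisons, Jun, Junb and Ifrd1 rose and Egr2, Egr3 and Dusp6 fell. Interferon-stimulated genes fell with 4-1BB and OX40 at both times (0.000323 to 0.013; 0.07 to 0.192 with an estimated correlation). Cytokines were called once, for DR3 at 18 h (10 of 22 higher, camera adjusted p 0.00188, and 0.0105 with an estimated correlation). The hypoxia response was called once, for OX40 at 36 h (camera adjusted p 0.0219, and 0.07 with an estimated correlation). That call also ended with the ribosomal locus share as a covariate (camera adjusted p 0.0577). Myeloid and dendritic markers were called once, for OX40 at 18 h (camera adjusted p 0.0431, and 0.119 with an estimated correlation). The TNF receptor superfamily, its ligands, chemokines and their receptors, cytotoxic, pro-apoptotic, cholesterol, ER stress, mitochondrially encoded, B cell, CD8 T, NK and gamma-delta T cell and helper T cell lists were not called with any agonist. The anti-apoptotic call for TNFR2 at 18 h ended without TNFR2 agonist replicate 3 (0.154), and the glycolysis call for DR3 at 36 h without control replicate 2 (0.0758). That of immediate early genes at 18 h ended for DR3 without control replicate 3 or DR3 agonist replicate 1 or 2 (0.0541 to 0.0795), and for OX40 without control replicate 1 or 3 or OX40 agonist replicate 1 (0.0522 to 0.498). The call of myeloid and dendritic markers ended without control replicate 3 (0.0835) or OX40 agonist replicate 1 (0.127). Without OX40 agonist replicate 1 the number of lists called for OX40 at 18 h was 9 instead of 14.

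Whether the effect of an agonist differed between the times was tested as an interaction. Costimulation acts on cells whose receptor levels and cycle stage change, so the same signal can meet a different cell. The difference was called for 958 genes with the TNFR2, 626 with the 4-1BB, 331 with the DR3 and 498 with the OX40 agonist. Nr4a1 and Nr4a2, early targets of T cell receptor signals, were lower with the TNFR2 agonist at 18 h (−0.38 and −0.62) and higher at 36 h (0.35 and 0.58). Eomes rose with each agonist at 18 h and not at 36 h, with interactions of −1.17 to −1.42. Without the 6 libraries richest in the ribosomal locus transcript the counts were 242, 245, 63 and 90, without the 5 richest the TNFR2, DR3 and OX40 counts were 471, 167 and 258, and with its share as a covariate the TNFR2 and OX40 counts were 508 and 235. The DR3 count was 204 without control replicate 1 at 18 h, 197 without DR3 agonist replicate 1 at 18 h and 209 without DR3 agonist replicate 2 at 36 h. The OX40 count was 921 without OX40 agonist replicate 1 at 18 h, 160 without replicate 2 at 18 h and 289 without replicate 3 at 36 h.

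Whether the agonists differed from each other was asked with a joint test at each time, which called 2045 genes at 18 h (14.3%) and 1297 at 36 h (9.1%). Since doses were not matched, these differences belong to the agonists as applied. With only the groups compared in the fit the count at 18 h was 1167; without the 6 or the 5 libraries richest in the ribosomal locus transcript the counts were 1351 and 1454 at 18 h and 688 and 723 at 36 h. Cacnb3 led at 18 h (adjusted p 2.97e-27): the log2 difference was −1.13 ± 0.06 for TNFR2 against 4-1BB, 1.81 ± 0.07 for 4-1BB against DR3 and 1.63 ± 0.07 for 4-1BB against OX40. Scin led at 36 h (1.61e-24), where 4-1BB exceeded DR3 by 1.08 on the log2 scale and OX40 by more than that (adjusted p 1.66e-22); at 18 h TNFR2 and 4-1BB did not differ (adjusted p 0.131) and neither did DR3 and OX40 (0.8). Csf2 was higher with 4-1BB than with TNFR2, DR3 or OX40 at 18 h, with log2 differences of −1.49 ± 0.15 for TNFR2 against 4-1BB and of 1.35 and 1.64 for 4-1BB against DR3 and OX40. Bhlhe40 was lower with DR3 than with OX40 at 18 h (−0.59 ± 0.04, adjusted p 4.95e-16), and Tigit lower with 4-1BB than with OX40 (−0.91 ± 0.05, adjusted p 4.93e-19). Of pairwise list tests, NF-kB target genes were higher with 4-1BB than with OX40 at both times (adjusted p 3.06e-08 and 7.06e-12), and cytokines lower with TNFR2 than with DR3 at 18 h (2.93e-06), all of which held with an estimated correlation.

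How alike the agonist effects were was asked across genes, which are not independent replicates. Agonists of the same time share their control libraries, which alone makes effects alike, so control and agonist libraries with no change between them were simulated together. A simulation around the mean of the real controls, planned at first, was not used, because the chance error of the controls cancels in it. At 18 h Pearson r between log2 fold changes ran from 0.57 (DR3 and OX40) to 0.69 (TNFR2 and 4-1BB), and at 36 h from 0.64 to 0.67, against simulated means of 0.44 to 0.51 and a highest simulated value of 0.58. The covariance was 0.112 to 0.209, against simulated means of 0.0465 to 0.0571. Effects of different agonists at different times, which share no library, had r of 0.25 to 0.42. TNFR2 and 4-1BB at 18 h shared 1339 genes called higher and 1447 called lower, where independent calls would give 287.1 and 287.2, and 4 genes were called in opposite directions. TNFR2 at 18 h and 4-1BB at 36 h, which share no library and had the highest r of such pairs, had 960 and 1081 in common. Independent calls would give 247.8 and 252.4, and 53 were in opposite directions. OX40 at 18 h and TNFR2 at 36 h, the pair with the most opposite calls, had 622 and 641 in common against 172.8 and 164.8, and 104 in opposite directions. All 8 comparisons called 315 genes higher and 315 lower, 630 in all. Among the 9636 genes with at least 5 CPM the correlations within a time were 0.82 to 0.91, against simulated means of 0.44 to 0.50 and a highest simulated value of 0.71.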

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

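The tests of cell cycle progress and of the ribosomal locus share given in this part were chosen after the result was seen, and the counts of other splits were planned. Each result named here stood out because the effect of an agonist differed between 18 h and 36 h in a test of the difference itself; values are the log2 effect at 36 h minus that at 18 h. No group held 4 or more libraries, so no test for a far library within a group was made. The effect of leaving out single libraries is given with the counts. List tests of the differences were repeated only with an estimated correlation. They were not repeated with the settings for the ribosomal locus or with a library left out, so how far they depend on these is not known.

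With the TNFR2 agonist the difference was called for 958 genes, 527 positive and 431 negative. Nr4a1 (0.73 ± 0.05, edgeR adjusted p 3.79e-14), Nr4a2 (1.19) and Ptpn22 (0.71), which report or restrain T cell receptor signals, moved upward, as did Sla (0.65), Tnfrsf9 (0.57) and the egress receptor S1pr1 (0.78). Pim2 (−0.72), Ncf1 (−0.68), Ly75 (−0.61) and Slc35b4 (−0.57) moved downward. Immediate early genes rose as a list (15 members positive and 3 negative, 17 and 4 adjusted over the list alone; camera adjusted p 2.54e-10, held at 0.0217 with an estimated correlation). The hypoxia response rose as well (7 positive and 2 negative, 0.000103; 0.00801 with an estimated correlation), and ribosome biogenesis fell (1 positive and 10 negative, 3.05e-10; 0.0217 with an estimated correlation).

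With the 4-1BB agonist the difference was called for 626 genes. Ly75 (−0.86 ± 0.05, adjusted p 3.25e-17), Ncf1 (−0.78), Slamf6 (−0.80), Cacnb3 (−1.68) and Slc35b4 (−0.59) were lower at 36 h than their effect at 18 h, and Tnfrsf9 (0.62), Nr4a2 (1.03), Gimap4 (0.63) and Acap1 (0.60) higher. With the DR3 agonist it was called for 331 genes, among them Eomes (−1.42 ± 0.13, adjusted p 9.44e-11), Ly75 (−0.55), Slc35b4 (−0.51), Igfbp4 (−0.83), Cacnb3 (−1.28), Gbp2 (−0.52), Thy1 (−0.46), Ncf1 (−0.50) and, upward, Txnip (0.62). NF-kB target genes moved downward with DR3 (1 positive and 8 negative, 1.54e-05; 0.0397 with an estimated correlation), with a median of −0.08 and a mean of 0.00, and so did cytokines (4 negative, 0.0011; 0.0249 with an estimated correlation). With the OX40 agonist it was called for 498 genes, among them Eomes (−1.34 ± 0.13, adjusted p 1.08e-09), Slc35b4 (−0.53), Gbp5 (−0.46), Pim2 (−0.50), Cacnb3 (−1.15), Lad1 (−0.45), Acap1 (0.51), Cyth4 (0.54) and Nr4a2 (0.75), and no list call held with an estimated correlation.

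For the number of interaction genes with the TNFR2, 4-1BB and DR3 agonists, the count of other splits could not decide about chance. Agonist and control libraries were exchanged within each time, and of 100 splits 7 gave as many genes as the real 918 with the TNFR2 agonist, as many as 906 with the 4-1BB agonist, and as many as 357 with the DR3 agonist, fitted on the groups compared. The highest of the others were 2154, 1472 and 1226. All 6 of those others kept the labels at 18 h whole and exchanged 2 of 3 libraries at 36 h, which leaves the agonist effect at 18 h in place and turns part of that at 36 h round. Such splits hold the agonist effect itself and not chance alone, so their share says nothing on the interaction. The highest of the remaining splits were 352, 265 and 139, but these mix agonist and control libraries within groups, which widens the spread. The OX40 agonist had 2 libraries at 18 h and was not split. Without the 5 libraries with over 11000 CPM of the ribosomal locus transcript, the counts were 471 for TNFR2, 167 for DR3 and 258 for OX40. With its share as a covariate they were 508 for TNFR2, 469 for 4-1BB, 267 for DR3 and 235 for OX40. The DR3 count was 204 without control replicate 1 at 18 h, 197 without DR3 agonist replicate 1 at 18 h and 209 without DR3 agonist replicate 2 at 36 h. The OX40 count was 921 without OX40 agonist replicate 1 at 18 h, 160 without replicate 2 at 18 h and 289 without replicate 3 at 36 h.

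Cell cycle genes were higher with each agonist at 18 h by the list tests with a preset correlation, none of which held with an estimated correlation (adjusted p 0.115 to 0.222 for S phase and 0.217 to 0.481 for G2 and mitosis). A share of ribosomal locus transcript that differed between libraries does not account for the median rise, since with that share as a covariate the median fold change of 62 S phase, G2 and mitosis genes kept at least 101% of its size in the 4 comparisons. Of the interaction calls of these genes 40 were negative (27, 4, 3 and 6 with the TNFR2, 4-1BB, DR3 and OX40 agonists) and 0 positive. That sign restates a rise at 18 h that was smaller at 36 h, so earlier progress along the course of the control cells, more dividing cells and better survival of dividing cells cannot be told apart here.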

How the results depend on the processing

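The 3 settings for the ribosomal RNA locus were chosen after the data were seen, and the limit of 11000 CPM was set after a limit of 10000 CPM had left 1 control library at 18 h. No named gene changed direction under an alternative while called, and no list call of the stimulation, control or agonist comparisons did. Joint tests have no direction. List tests of the time interactions and of pairs of agonists were repeated only with an estimated correlation. With DESeq2, RLE size factors, no filter, the stricter filter and the replicate block, all 17 counts of changed genes stayed within 1.5 times their value.

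A minimum fold of 2 left 5805 and 6749 genes for stimulation at 18 h and 36 h, 1105 between the controls, 411, 470, 230 and 219 for the TNFR2, 4-1BB, DR3 and OX40 agonists at 18 h, 265, 349, 127 and 143 at 36 h, and 42, 34, 25 and 28 for their time interactions, because a further condition was added. With the 6 libraries over 10000 CPM left out, the agonists changed 1876, 1873, 1150 and 1181 genes at 18 h, the interactions 242, 245, 63 and 90, and the joint tests called 1351 genes at 18 h and 688 at 36 h. This setting keeps 1 control library at 18 h, assumed to vary like the other groups. It changes both the number of samples and the share of the transcript, and which of these lowered the counts was not tested. With the 5 libraries over 11000 CPM left out, TNFR2 at 18 h changed 2945 genes, the TNFR2, DR3 and OX40 interactions 471, 167 and 258, and the joint test at 36 h called 723. With the share as a covariate the TNFR2 and OX40 interactions had 508 and 235 genes; the cause was not tested. With only the groups compared in the fit, the joint test at 18 h called 1167; the cause was not tested.

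Estimated correlations between genes, which widen the test, left 7, 7 and 10 lists called for stimulation at 18 h, at 36 h and between controls, 3, 2, 4 and 2 for the agonists at 18 h, and 2, 4 and 1 for TNFR2, 4-1BB and OX40 at 36 h. Among genes with a mean of at least 5 CPM, r was 0.89 for TNFR2 and 4-1BB, 0.91 for TNFR2 and DR3, 0.84 for 4-1BB and DR3, 0.86 for 4-1BB and OX40 and 0.82 for DR3 and OX40 at 18 h. At 36 h it was 0.88 for TNFR2 with 4-1BB or DR3, 0.86 for TNFR2 and OX40, 0.85 for 4-1BB and DR3, 0.89 for 4-1BB and OX40 and 0.86 for DR3 and OX40; the cause was not tested.

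Leaving out each library gave 11126 to 11317 genes for stimulation at 18 h, 11704 to 11901 at 36 h and 6787 to 6916 between controls. At 18 h the ranges were 3535 to 4598 for TNFR2, 2994 to 3208 for 4-1BB, 2151 to 2525 for DR3 and 1491 to 2534 for OX40; at 36 h they were 2403 to 3418, 2458 to 2982, 1191 to 1792 and 1373 to 1752. The interactions gave 687 to 1133, 473 to 593, 197 to 334 and 160 to 921, and the joint tests 1436 to 2640 at 18 h and 968 to 1385 at 36 h. Without an OX40 agonist library at 18 h the lone sample is assumed to vary like the other groups. Lists called numbered 16 to 16, 14 to 16 and 18 to 20 for the stimulation and control comparisons, 13 to 14, 12 to 14, 12 to 14 and 9 to 14 at 18 h, and 9 to 12, 9 to 11, 6 to 7 and 9 to 9 at 36 h.

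These totals do not say which lists. Of 138 list calls RLE ended 3, the replicate block 5, the covariate 3, leaving out 6 libraries 5 and leaving out 5 libraries 8, at adjusted p of 0.0502 to 0.277, and the estimated correlation ended 91. They were calls of immediate early genes (DR3 and OX40 at 18 h), the IL-2 and STAT5 response, oxidative phosphorylation, anti-apoptotic genes, inhibitory receptors, myeloid and dendritic markers, the hypoxia response and ER stress, apart from those under the estimated correlation. Leaving out each library kept 791 and ended 23, which the report names.

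Of the named genes, DESeq2 kept 1556 calls on their side of the threshold and moved 24 below and 7 above it, RLE 1605, 7 and 3, no filter 1576, 32 and 7, the stricter filter 1509, 3 and 3, the smaller fit 1533, 18 and 20, and the replicate block 1602, 11 and 2. The counts were 1500, 114 and 1 without 6 libraries, 1562, 46 and 5 without 5, and 1566, 44 and 5 with the covariate. Leaving out each library kept 9524, moved 290 below and 33 above.

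Replicate numbers might mark a shared day or animal, so the replicate block was tried. It gave 11562, 12060 and 7414 genes for stimulation and controls, 4373, 3641, 2740 and 2617 for the agonists at 18 h, 3515, 3167, 1900 and 1915 at 36 h, and 922, 594, 292 and 425 for the interactions. Libraries with the same number had correlated residuals of −0.167 to 0.161 (median −0.008), and 2 of 32 libraries correlated best with their own number.

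What depth limits was not tested by varying it; on simulated data with 3 libraries, 42% of genes changed 1.2-fold were recovered for the 4-1BB agonist at 36 h against 100% at 2-fold.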

Other observations

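The tests of the ribosomal locus share, of shared controls, of structural RNAs and of dendritic cells given in this part were chosen after the result was seen, and those of gene length and other splits before. Some of the genes with the largest falls were these, of which Fgl2 is on the list of effector Treg genes and the others are on no list. Fgl2, a secreted effector of Treg suppression, fell in all 8 comparisons, with log2 fold changes of −1.74 and −1.55 for the 4-1BB agonist at 18 h and 36 h. The membrane protein gene Emp1 and the protease inhibitor gene Ctla2a fell by −1.86 to −0.78 and −1.70 to −0.56 on the log2 scale over the 8 comparisons. At 36 h the motor protein gene Myo6, the actin oxidase gene Mical2 and Xdh, which makes uric acid, fell with each agonist (−1.74 to −1.25, −2.08 to −1.04 and −1.42 to −1.01).

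Zbtb46, Ly75, Cd83, Cd80 and Ccr7, genes also known from dendritic cells and picked after their values were seen, rose with each agonist. The fixed list of myeloid and dendritic markers was called in 1 of 8 comparisons, OX40 at 18 h (adjusted p 0.0431; 0.119 with an estimated correlation). Ly75 (ENSMUSG00000026980, chromosome 2, 60292103 to 60383303) rose by 0.68 to 1.40 at 18 h and 0.20 to 0.54 at 36 h, and Zbtb46 (ENSMUSG00000027583, chromosome 2, 181387762 to 181459426) by 1.08 to 2.11. Cells of the dendritic lineage in the agonist cultures would bring the class II genes H2-Aa, H2-Ab1 and H2-Eb1, which are among their most abundant. In 0 of 8 comparisons did these 3 genes together rise by more CPM than Zbtb46: their sum was at most 7.52 CPM and changed by −1.22 to 3.25 CPM, while Zbtb46 rose by 6.11 to 35.4 CPM. With OX40 at 18 h, where the list of markers was called, the sum fell from 3.94 to 2.72 CPM while Zbtb46 rose by 20.7 CPM. Cd74, as abundant in dendritic cells, did rise in all 8, from 45.87 to 86.17 CPM with TNFR2 at 36 h. The class II sum went from 4.27 to 7.52 CPM in that comparison, and dendritic cells would bring the class II genes with Cd74. Resting libraries held 67.94 CPM of Cd74, but which cells it came from was not tested. The Foxp3-GFP sort selects against such cells before culture. Transcripts known from other cells were still present in resting libraries, with 190 counts of the myeloid receptor Csf1r, so the sort alone does not exclude them. A candidate explanation that stays open is that these genes share NF-kB control in both cell types; no test of NF-kB binding could be made with these data.

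The 630 genes called in the same direction in all 8 comparisons might reflect the libraries rather than the agonists. After a trend with gene length was removed, 580 (92.1%) were still called in the same direction in all 8, which argues against length bias as the whole cause. With the share of ribosomal locus transcript as a covariate 497 (78.9%) were, and all 630 kept their sign. Chance values of the control libraries would not carry over between the times, which used other controls, so genes called with all 4 agonists at both times would go in opposite directions about as often as in the same one. Of 632 such genes 2, Pim2 and Tnfrsf9, named after their values were seen, did, which argues against this as the cause of the set. Of 15 tested genes of short structural RNAs 1, Rpph1, was called in all 8, so a different carry-over of such RNAs cannot be told apart from an agonist effect for that gene. A common step such as NF-kB signalling stays open as a biological explanation, and so does any handling shared by agonist wells and not by control wells, because the labels give no batch.

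Splits of 3 against 3 libraries number 10, too few for a share under 0.05. Fitted on the groups compared, the real counts were 10925 and 11409 genes for stimulation at 18 h and 36 h and 7526 between controls, 4219, 4631 and 2622 for the TNFR2, 4-1BB and DR3 agonists at 18 h, and 3650, 3414, 2229 and 1821 for TNFR2, 4-1BB, DR3 and OX40 at 36 h. The highest of the other splits was 1 gene for DR3 at 36 h and 0 in each of the others, so 1 split of 10 was as large. For the joint test at 36 h, 1 of 100 splits, the real one, gave as many as 1850 genes and the highest of the others 77. This argues against a chance assignment of these libraries to the groups. The other splits mix agonists within groups, which widens the spread and lowers their counts. A difference between cultures that the replicates of a group share would pass this test too, so such a difference is not excluded.

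Erythrocyte transcripts were traces. Hbb-bs had 85 counts over the resting libraries, 25 over the controls at 18 h and 0 to 2 over each agonist group at 18 h. Hba-a1, which shares reads with its copy Hba-a2, had 27, 6 and 0. The platelet gene Itga2b was at 2.672 ± 0.451 CPM in resting cells and 1.078 ± 0.376 CPM in controls at 18 h.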
